A study of Mus musculus with 2 samples.

How the data were processed

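Single-cell RNA libraries were made from bone marrow of aged C57BL/6J mice given gut microbiota from young donors (FMT_young) or aged donors (FMT_aged), with 1 library in each group. Per the labels, flow-sorted whole marrow, lineage-negative and lineage-negative Kit-positive cells were combined in parts of 1 to 1 to 4 and prepared with the 10x Genomics Chromium 3' kit v3. The number of animals in a library is not stated there. The deposited matrices hold counts, as raw UMI counts per gene and barcode without normalization. They come from Cell Ranger with mm10 per the submitters' processing notes, version 3.1.0 per the file headers. The deposited lists of genes and barcodes, of unit other, hold names and no measurement, 31053 genes and 6794880 barcodes for each library. All barcodes of the kit are in the files, so cells were called here with 1 rule for both libraries.

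A barcode was called as a cell with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. Of 13922 FMT_young and 14000 FMT_aged barcodes with 1000 UMIs or more, which held 94.8% and 95.8% of all UMIs, 13.9% and 18.7% were over the mitochondrial limit. This called 11932 and 11351 cells. Doublet scores were computed in each library with a reimplementation of the Scrublet score (30 principal components, 2 simulated doublets per cell), and the highest-scoring 0.8% per 1000 called cells were removed, 1139 (9.55%) and 1031 (9.08%) cells. The 10793 and 10320 kept cells held 159392301 and 158212687 UMIs, with medians of 2.61% and 2.94% mitochondrial UMIs.

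Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together on 2000 variable genes seen in at least 10 cells, with 40 principal components, 20 exact nearest neighbours, a shared-neighbour graph and the Leiden method at resolution 1.0, without batch correction. Clusters were named from marker lists of 17 cell types fixed before the data were examined. A name needed at least 3 markers that were present in 10% of the cluster's cells and 1.5 times higher than elsewhere, and the cluster stayed unnamed where its 10 leading genes held none of its own markers or more markers of another type. The marker genes were fixed ahead, but these thresholds, the treatment of ties and the Kit limit below were set after the clusters had been looked at. In a tie a cluster kept its name with at least 2 own markers among the leading genes and lost it with fewer. The HSC-like cluster is such a tie, with 2 HSC markers (Hlf and Meis1) and as many MPP markers (Sox4 and Adgrl4), so its name rests on a rule chosen with it in view, and had every tie lost its name no HSC-like class would have been compared. Had every tie kept its name, clusters 12 and 16, with Cd34 tied against 1 marker of another type, would have been MPP-like. The planned union of HSC-like and MPP-like cells was therefore replaced, after seeing the data, by the HSC-like class with these 2 clusters. Names such as HSC-like describe transcripts and not a sort gate. Monocyte and neutrophil clusters in which at least 20% of cells had a UMI of Kit were called progenitors. All clusters past that limit formed the progenitor denominator, except lymphoid, dendritic, macrophage, B, plasma, late erythroid and stromal ones.

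Shares were given with exact Clopper-Pearson intervals. In each class the UMIs of all cells of a library were summed and given as CPM, counts scaled to the same total of the class, with exact Poisson intervals, and the log2 ratio of FMT_young over FMT_aged had an exact conditional binomial interval. All intervals are at 95%. Those of shares, CPM and ratios cover counting error only, while those of list medians, given below, describe the spread among the members of a list. With 1 library per group no test, standard error or count of changed genes was computed, and cells were not treated as replicates. Ratios with a count of 0 used a prior count of 0.5 and entered list medians in that form, while ranking used the interval bounds, which hold no prior. The alternatives with free RNA subtraction and with means over cells, listed below, added the prior to every gene.

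Genes were named by a rule fixed before the data were examined. In the HSC-like class, among genes with at least 30 UMIs in both libraries together and at least 50 CPM in the higher library, the 10 in each direction with the interval bound farthest from 0 on its near side were named. In every other named class with at least 50 cells per library, the 3 in each direction were named among genes with at least 100 UMIs. In each list the 2 members in each direction by the same bound were named. Unnamed gene models, ribosomal protein and mitochondrially encoded genes were given as groups, and genes that lead a class's cluster were left to its description. Of the named gene IDs, 127 of 127 were found in GENCODE vM21 (GRCm38), from which positions were taken.

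The 25 gene lists were fixed before the data were examined. They cover type I interferon response, interferon gamma response, TNF and NF-kB response, IL-1 and IL-6 signalling, immediate early and dissociation stress, heat shock and unfolded protein response, HSC identity, genes higher in HSCs of old mice, myeloid, lymphoid, erythroid and megakaryocyte priming, FoxO signalling, p53 and DNA damage, S phase, G2 and M phase, oxidative phosphorylation, glycolysis and hypoxia, mTOR, Myc and ribosome production, MHC class II presentation, aryl hydrocarbon receptor targets, autophagy and lysosome, apoptosis regulation, free RNA sources and a sex-linked check of the library. Members with at least 10 UMIs in both libraries together entered the median, which had an order-statistic interval and a percentile among 10000 random lists of the same size, each member replaced by 1 of the 100 genes nearest in expression. For shares of cells with at least 3 genes of a list, each cell was thinned to 2000 UMIs and cells below that were left out, with unthinned shares beside them. Leading V and constant genes were counted in plasma cells with at least 10 UMIs of the kind. The free RNA profile was the sum of barcodes with under 100 UMIs.

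Alternatives fixed before the data were examined were a minimum of 500 UMIs and 250 genes, of 2000 UMIs, or a UMI minimum set per library, mitochondrial limits of 5% and 20%, no doublet removal, resolutions 0.5 and 2.0, classes by marker score per cell, separate clustering of each library, TMM scaling (30% and 5% trimmed), totals without ribosomal, mitochondrial and globin genes, means over cells, free RNA subtraction, list minimums of 50 and 1 UMIs, HSC-like cells by transcripts (UMIs of at least 2 of Hlf, Mecom, Procr, Slamf1, Hoxb5, Fgd5 and Tcf15 and none of Mpo, Elane, Klf1 and Car1) and unthinned counts. Free RNA was subtracted from the sum of the HSC-like class, in the share that granule and globin genes allow, and not cell by cell as first set down. Chosen after seeing the data were clustering without immunoglobulin, histone, interferon, immediate early and cell cycle genes, the HSC-like class with the 2 unnamed clusters that have Cd34 among their leading genes, the HSC-like class without its 1% of cells richest in interferon genes, and shares without the shallow GMP-like cluster, without the other unnamed clusters, or without plasma cells with at least 10 UMIs of Igkv1-117.

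The ratios were tested on simulated data drawn from the HSC-like class, with 11279 genes. Each gene's count was an independent Poisson draw, the model that the interval assumes. Clumping of UMIs in single cells and shared shifts of genes were not simulated, so coverage and list percentiles under them were not tested. The interval covered the true value for 95.7% of 11082 unchanged genes and for 91.8% to 100.0% of genes changed by 1 or 2 on the log2 scale. Of 100 simulated lists of 30 genes without a difference, 2.0% lay outside the central 95% of random lists, and of lists shifted by -0.4, 100.0% did. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, on a single thread with fixed seeds.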

Results

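Bone marrow cells of aged C57BL/6J mice that had received gut microbiota from young donors (FMT_young) or from aged donors (FMT_aged) were profiled by 10x Genomics single-cell RNA sequencing, with 1 library per group. Each library was a sorted mix of whole marrow, lineage-negative and lineage-negative Kit-positive cells in parts of 1 to 1 to 4, and the labels do not say how many animals went into it. FMT_young held 214982156 UMIs and FMT_aged 207642851. After cell calling, 10793 and 10320 cells remained, with medians of 11093 and 11688.5 UMIs and of 2442 and 2816 genes per cell. Ratios are FMT_young over FMT_aged on the log2 scale. Intervals of shares and of single genes are 95% intervals that cover counting error only. Intervals of list medians are 95% order-statistic intervals that describe the spread among list members. With 1 library per group there was no replicate check and no test between the groups, so the values below compare these 2 libraries.

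Stem-like and progenitor clusters made up most of both libraries, as the sort mix sets. The HSC-like class held a lower share of the FMT_young library and the granulocyte-monocyte progenitor (GMP)-like class a higher share. HSC-like cells were 6.91% of FMT_young cells (746 cells, interval 6.44 to 7.41%) and 9.67% of FMT_aged cells (998 cells, 9.11 to 10.3%), a log2 ratio of -0.48 (-0.62 to -0.35). GMP-like cells were 28.1% and 21.6% (0.38, interval 0.30 to 0.46). Among the Kit-expressing progenitor clusters alone, 6515 and 6302 cells, the HSC-like share was 11.5% and 15.8% (-0.47) and the GMP-like share 46.6% and 35.4% (0.40, but 0.03 with up to 20% mitochondrial UMIs allowed, 0.09 at resolution 2.0 and 0.09 with separate clustering). Monocyte progenitor-like cells were 22.5% and 25.8% of these clusters (-0.20, but 0.11 at resolution 2.0, 0.08 with at least 2000 UMIs, 0.03 with a UMI minimum set per library and 0.03 in the clustering without the gene families named below). Basophil, eosinophil or mast cell-like cells were 4.64% and 7.36%, and neutrophil progenitor-like cells 2.76% and 2.63% (0.07, or -0.04 to 0.90 over 13 alternatives).

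The HSC-like share depended on how the class was drawn. At the finer clustering resolution of 2.0, a smaller HSC-like class of 165 and 146 cells gave a log2 ratio of 0.11. When immunoglobulin, histone, interferon, immediate early and cell cycle genes were kept out of the clustering, 135 cells in each library were HSC-like, a ratio of -0.06. Clustering each library on its own put 715 FMT_young cells but 83 FMT_aged cells in the class, a ratio of 3.04. The GMP-like ratio among all cells ran from 0.09 to 0.49 in 14 alternatives, with 0.09 at resolution 2.0. It was 0.10 with up to 20% mitochondrial UMIs allowed, 0.10 without doublet removal and 0.11 with a UMI minimum set per library. It was 0.17 without a shallow cluster of 1001 FMT_young and 401 FMT_aged cells with medians of 2602 and 2959 UMIs, in which granule genes such as Elane, Prtn3 and Mpo led beside the immunoglobulin gene Ighg2c. The GMP-like clusters did not all go the same way. The ratio was 1.26 in this shallow cluster and 0.84 in cluster 10 (567 and 302 cells). It was -0.20 (-0.34 to -0.06) in cluster 2 and -0.03 in cluster 5.

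Among mature and committed cells, plasma cell-like cells were 10.5% of FMT_young and 6.62% of FMT_aged cells (0.66), and this turned to 3.43% and 6.6% (-0.95) without plasma cells rich in Igkv1-117 of either library, 787 and 2 cells, described further on. T, NK or innate lymphoid-like cells were 9.59% and 14.4% (-0.58, or -2.04 to -0.05 over 14 alternatives), mature B-like cells 3.03% and 4.96% (-0.71), and basophil, eosinophil or mast cell-like cells 2.80% and 4.50% (-0.68). The mature B-like ratio was 0.08 when cells were limited to 5% mitochondrial UMIs, and the basophil, eosinophil or mast cell-like ratio was 0.07 in the clustering without the gene families named before. Monocyte-like cells were 3.60% and 2.67% (0.43, or 0.03 with classes by marker score), neutrophil-like cells 7.0% and 5.86% (0.25), conventional dendritic-like cells 2.63% and 3.28% (-0.32, or 0.01 without doublet removal) and plasmacytoid dendritic-like cells 1.28% and 0.514% (1.32, from 138 and 53 cells, or 0.37 with classes by marker score). Monocyte progenitor-like cells were 13.6% and 15.8% of all cells (-0.21, or 0.03 in the clustering without the gene families). Neutrophil progenitor-like cells were 1.67% and 1.61% (0.05, or -0.22 to 0.68 over 13 alternatives). The macrophage-like cluster was led by globin genes as well as C1qa, C1qb and C1qc. Hbb-bs stood in it at 6219 CPM in FMT_young and 124 in FMT_aged, so its share is not compared. Clusters left without a name were 7.76% and 7.91%. Plasma cells lay mostly in cluster 9 in FMT_young and in cluster 8 in FMT_aged, and mature B cells mostly in cluster 19 and in cluster 17.

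**Figure D1:**
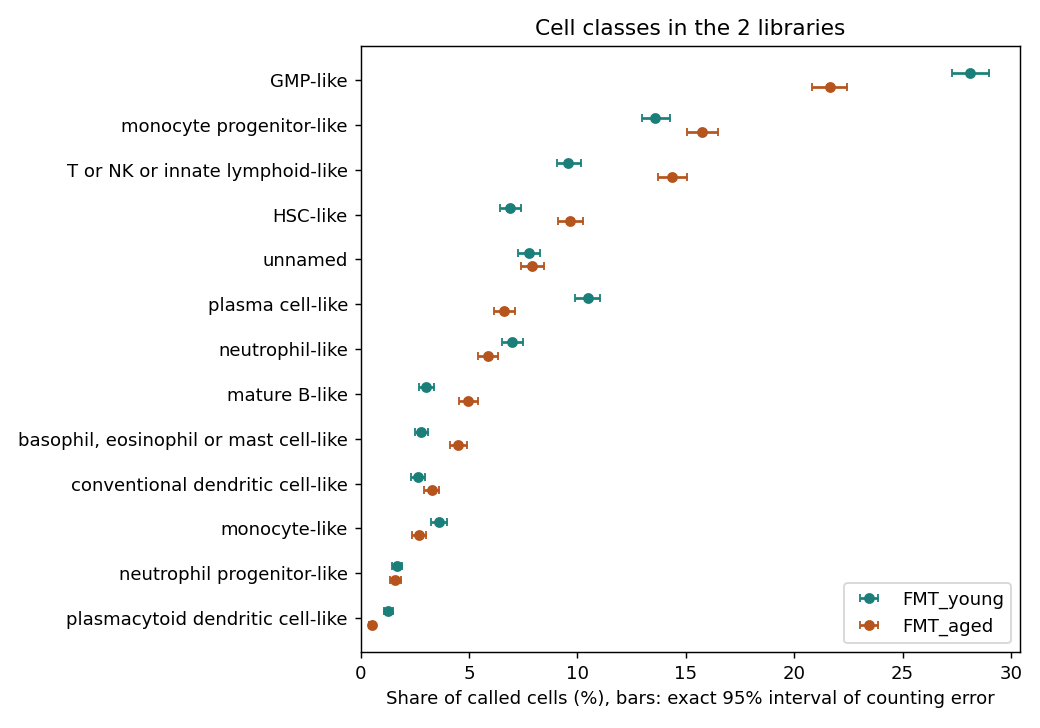
Share of called cells in each class for both libraries, with exact intervals of counting error. The macrophage-like cluster is left out because globin genes that lead it differ between the libraries.

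HSC-like cells of the FMT_young library had more transcript of immediate early transcription factors and less of interferon-induced genes. The class is a broad stem and multipotent progenitor set, whose leading genes include Myl10, Hlf, Meis1, Adgrg1, Sox4, Angpt1, Ifitm1 and Adgrl4. HSC and MPP markers were tied among its 10 leading genes, and it kept the HSC-like name by a treatment of ties set after the clusters had been looked at. Myl10, a myosin light chain gene and first among them, had 285 CPM in FMT_young and 510.0 in FMT_aged (-0.84, -0.92 to -0.76). Class sums were 6638412 UMIs in FMT_young and 9169179 in FMT_aged. The median ratio of 12808 genes was -0.12, so most genes lay slightly below 0.

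Klf2, a Krüppel-like factor that keeps T cells quiescent and acts downstream of FoxO1, had the highest ratio by the naming rule, with 1637 CPM in FMT_young and 248 in FMT_aged (2.72, interval 2.66 to 2.79). Its gene ENSMUSG00000055148 lies on chromosome 8 at 72319033 to 72321656 (GRCm38). Nr4a1, an orphan nuclear receptor that restrains HSC proliferation, had 271 and 43.2 (2.65, 2.49 to 2.81; ENSMUSG00000023034, chromosome 15, 101254269 to 101274795). Ccl4, a chemokine of the NF-kB response, had 533 and 124 (2.10, 2.0 to 2.20). Dennd4a, a guanine exchange factor for Rab10, followed with 253 and 68.5 (1.88), Rgcc, a regulator of CDK1 activity, with 108 and 30.2 (1.83), and Skil, a repressor of TGF-beta signalling, with 135 and 41.3 (1.71). Dusp5, a nuclear phosphatase of ERK, had a ratio of 1.62, the antiproliferative p53 target Btg2 1.60, the Krüppel-like factor Klf6 1.54 and the small GTPase gene Rhob 1.52. These 10 genes were higher in FMT_young in all 17 alternatives, with lowest values between 0.54 for Dennd4a and 1.82 for Ccl4. Clustering each library on its own, which changed the HSC-like class most, gave Klf2 a ratio of 1.70.

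Genes higher in the FMT_aged library had smaller ratios. AY036118, an RNA from a locus with ribosomal RNA sequence, had 38.3 CPM in FMT_young and 101.5 in FMT_aged (-1.41, interval -1.61 to -1.21; ENSMUSG00000105361, chromosome 17, 39847113 to 39848035). Lars2, the mitochondrial leucyl-tRNA synthetase gene, had 136 and 323 (-1.25, -1.36 to -1.14; ENSMUSG00000035202, chromosome 9, 123366927 to 123462666). Together with Gm42418 these genes took 0.239% of HSC-like UMIs in FMT_young and 0.607% in FMT_aged (-1.34), and the same 3 genes were lower in FMT_young in all 13 classes (-0.84 to -1.47). In barcodes with under 100 UMIs Lars2 stood at 210 and 473 CPM (-1.17), near its ratio in HSC-like cells. Whether its UMIs come from the synthetase transcript was not tested. Clec2d, a ligand of the NK receptor Nkrp1d, had 58.8 and 119.7 (-1.03). The histone gene Hist1h2ac (-0.87), the fatty acid importer of mitochondria Cpt1a (-0.76), the interferon gamma-induced serpin Serpina3g (-0.64), the type I interferon-induced Ifi27 (-0.60) and the splicing-linked Rsrp1 (-0.58) were also lower in FMT_young. Dntt, the terminal transferase of lymphoid progenitors, had 158 and 286 (-0.86), and the beta globin gene Hbb-bt 39.5 and 72.1 (-0.87). Both had the opposite sign in some alternatives, and the cause was not tested. Dntt was at 0.36 with up to 20% mitochondrial UMIs allowed, 0.07 without doublet removal, 1.08 with classes by marker score and 4.71 with separate clustering. Hbb-bt was at 0.08 at resolution 2.0 and 0.62 in cells chosen by HSC transcripts. Ifi27 had no difference (0.0002) with separate clustering. Over 17 alternatives Cpt1a ran from -0.93 to -0.19 and Serpina3g from -1.07 to -0.15.

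**Figure D2:**
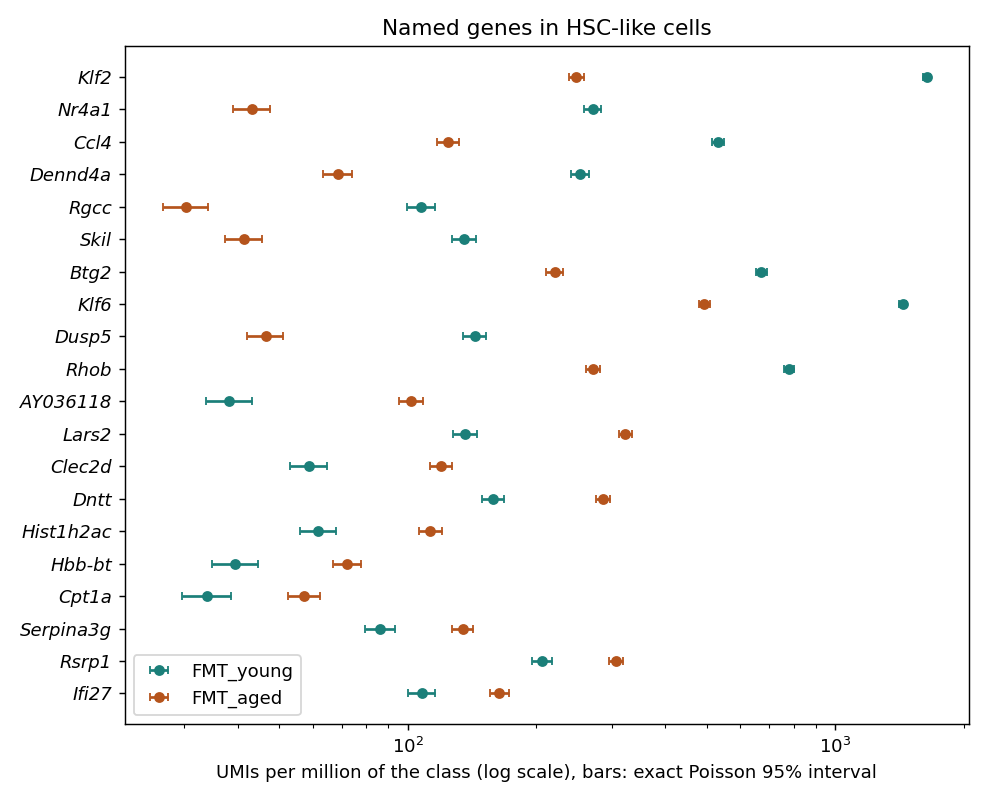
Genes named by the fixed rule in the HSC-like class, as CPM in each library with exact Poisson intervals.

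Inflammatory gene lists went in different directions in the HSC-like class. Of 36 type I interferon response genes, 33 were lower in FMT_young, with a median ratio of -0.37 (order-statistic interval -0.49 to -0.20), below all 10000 expression-matched random lists, whose central 95% ran from -0.19 to -0.01. The interval lay below 0 for 21 members and above 0 for 0. Besides Ifi27, these included the interferon-induced genes Isg15 (125 and 231 UMIs, -0.42), Irf7 (73 and 157, -0.64), Rtp4 (144 and 333, -0.74), Oasl2 (190 and 377, -0.52), Ifi27l2a (184 and 376, -0.57) and Zbp1 (61 and 134, -0.67), a sample chosen after the values were seen. Mx1, an antiviral GTPase, had 5 UMIs in FMT_young and 37 in FMT_aged, the latter from 32 cells (-2.42, -4.13 to -1.07). Ifit3 had 6 and 43 UMIs (-2.38), but 24 of the 43 came from 1 cell. Among the 92 and 133 cells chosen by HSC transcripts, the median of the list was -0.09 (-0.26 to 0.09), within matched random lists, and it was -0.19 with the Cd34 progenitor clusters added and -0.63 with separate clustering. With each cell thinned to 2000 UMIs, UMIs of at least 3 of these genes were seen in 80.4% of FMT_young and 87.2% of FMT_aged HSC-like cells, against 17.7% and 12.2% of plasma cells, whose thinned counts hold fewer other UMIs because immunoglobulin genes take most of them. The unthinned shares were 99.6% and 100% against 92.4% and 89.5%, at medians of 7688 and 7986 UMIs in HSC-like cells and 13880 and 14460 in plasma cells.

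Of 34 interferon gamma response genes, 26 were lower in FMT_young (median -0.16, the 3.09th percentile of random lists), Serpina3g and the peptide transporter gene Tap2 (-0.45) among them. Cd74 (0.47) and Socs1 (0.65) were higher. With TMM scaling the median was -0.06. The TNF and NF-kB list went the other way, with 22 of 28 genes higher in FMT_young and a median of 0.46 (0.15 to 0.89), above all random lists. Ccl4 and the inflammasome sensor Nlrp3 (90 and 21 UMIs, 2.57) led it, while the chemokine Cxcl2 (-0.88) and the superoxide dismutase Sod2 (-0.25) were lower. IL-1 and IL-6 signalling genes were mixed, 10 higher and 15 lower (median -0.14), with Nlrp3 and Socs3 (0.69) higher and Myd88 (-0.48) and Pim1 (-0.20) lower.

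All 28 immediate early and dissociation stress genes were higher in FMT_young HSC-like cells, with a median of 1.10 (0.82 to 1.5) and 27 intervals above 0. Klf2 and Nr4a1 had the largest ratios, and the median was 0.49 with separate clustering. Heat shock and unfolded protein response genes were higher for 24 of 27 (median 0.18), with the chaperone genes Dnajb1 (0.91) and Hspa5 (0.82) leading and the asparagine synthetase gene Asns (-0.53) lower. FoxO signalling genes were divided, 22 higher and 19 lower (median 0.02, the 99.93rd percentile of random lists). Klf2 and Gadd45b (1.31) stood at the upper end, and Il7r (-0.67) and Smad3 (-0.59) at the lower.

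Lineage priming lists differed mainly for myeloid genes. Of 30 such genes, 25 were higher in FMT_young HSC-like cells (median 0.26, 0.16 to 0.40), among them the neutrophil elastase gene Elane (0.72) and Cd68 (0.71), while Hk3 (-0.39) and Nkg7 (-0.30) were lower. That median was -0.01 at resolution 2.0, -0.04 in cells chosen by HSC transcripts and -0.06 in the clustering without the gene families. Cells chosen by HSC transcripts were picked without UMIs of Mpo and Elane, which belong to this list, so their value is partly set by the choice. Lymphoid priming genes were mostly lower, 20 of 26 (median -0.11, the 41.2nd percentile of random lists), with Dntt and the recombinase gene Rag2 (7 and 27 UMIs, -1.48) lower and the B cell genes Cd79a (2.25) and Ighm (0.94) higher. This median was 0.25 with up to 20% mitochondrial UMIs allowed, 0.05 with at least 2000 UMIs, 0.09 without doublet removal and 0.98 with separate clustering. Ighm was also higher in FMT_young in barcodes with under 100 UMIs (30810 and 14110 CPM), so its ratio need not reflect priming of HSC-like cells. Erythroid genes were lower for 16 of 20 (median -0.21, the 6.49th percentile, or 0.06 at resolution 2.0), with Hba-a2 at 0 and 16 UMIs, Hbb-bs at 7 and 64, and the transferrin receptor gene Tfrc (0.64) higher. Megakaryocyte genes were split 11 to 9 (median 0.07, the 99.55th percentile of random lists), with Plek (0.81) and Mef2c (0.35) higher and Vwf (-0.81) and Itga2b (-0.48) lower, and the median ran from -1.34 to 0.17 in 19 alternatives.

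Stem cell identity genes were also split, 17 higher and 16 lower (median 0.00, the 97.97th percentile of random lists), and the median ran from -1.25 to 0.10 in 19 alternatives, with the lowest value from separate clustering. The cell cycle inhibitor Cdkn1c (1.11) and Gata2 (0.48) were higher in FMT_young, and Txnip (-0.35) and Tal1 (-0.31) lower. Of 38 genes known to be higher in HSCs of old mice, 21 were higher in FMT_young and 17 in FMT_aged (median 0.07, interval -0.19 to 0.24, the 99.99th percentile of random lists, which ran from -0.21 to -0.01). The lamin gene Lmna (1.45) and Jun (0.86) were higher, while Enpp5 (-0.85) and the platelet-bias gene Vwf were lower. The median of that list was -0.24 at resolution 2.0 and -2.19 with separate clustering.

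Cell cycle lists were lower in FMT_young HSC-like cells, 38 of 44 S phase genes (median -0.22, the 0.02nd percentile of random lists) and 42 of 52 G2 and M phase genes (-0.20, the 1.08th). Pcna (-0.45), Ubr7 (-0.59), Cdk1 (-0.84) and Cenpf (-0.77) were lower, and the histone-linked genes Nasp (0.51) and Slbp (0.34) higher. At resolution 2.0 these medians were 0.02 and 0.01, and with separate clustering 1.87 and 0.78. In the clustering without the gene families they were 0.16 and -0.28. Per cell, after thinning, UMIs of at least 3 G2 and M phase genes were present in 60.3% (56.7 to 63.9%) of FMT_young and 61.8% (58.7 to 64.8%) of FMT_aged HSC-like cells, with 8 and 3 shallower cells left out. Plasma cells had 6.92% and 7.36%, but immunoglobulin genes take 61.2% and 60.2% of their UMIs, so their thinned share is low by construction and gives no background level for HSC-like cells. Without thinning the shares were 95.4% and 97.1%, and 82.7% and 76.0% in plasma cells, at the median depths given for the interferon genes. Thinned shares in the progenitor classes were 92.0% and 94.2% for GMP-like, 93.3% and 93.3% for monocyte progenitor-like, 97.8% and 97.0% for neutrophil progenitor-like and 78.9% and 87.8% for basophil, eosinophil or mast cell-like cells. Unthinned they were 97.4% and 99.3%, 99.9% and 100%, 100% and 100%, and 98.0% and 99.1%. Thinning left out 372 of 3036 FMT_young and 91 of 2232 FMT_aged GMP-like cells, a larger part in FMT_young. The GMP-like, monocyte progenitor-like and neutrophil progenitor-like shares lie near 100%, which leaves little room for a difference.

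Metabolic lists had medians close to that of all genes, but oxidative phosphorylation genes lay low among expression-matched lists. Nuclear-encoded oxidative phosphorylation genes were lower for 39 of 47 (median -0.11, the 2.5th percentile of random lists), with 27 intervals below 0 and 3 above. Ndufb7 (-0.31) and Ndufb9 (-0.29) were lower the most, with Atp5k (0.30) and Ndufa3 (0.29) higher, and the median was 0.25 with separate clustering. Glycolysis and hypoxia genes were 11 higher and 18 lower (-0.07, or -0.18 to 0.33 in 19 alternatives), with Slc2a3 (0.99) and Vegfa (0.94) higher and Pdk1 (-0.42) and Pkm (-0.18) lower. The mTOR, Myc and ribosome production list was 11 to 17 (-0.03, or -0.10 to 0.59 in 19 alternatives), with Odc1 (0.29), Ddx21 (0.16), Dkc1 (-0.35) and Npm1 (-0.16) at its ends. Autophagy and lysosome genes were 6 to 20 (-0.09), with Ctsl (0.64), Sqstm1 (0.62) and Lamp1 (-0.17). Apoptosis regulators were 8 to 14 (-0.07), with Pmaip1 (1.92), Mcl1 (0.59), Xiap (-0.46) and Casp8 (-0.34), and p53 and DNA damage genes 12 to 19 (-0.09), with Btg2 and Pmaip1 higher and Chek1 (-0.39) and Sesn1 (-0.39) lower. TMM scaling, which shifts all genes by 0.10, turned the medians of the last 4 lists and of glycolysis and aryl hydrocarbon receptor genes to 0.07, 0.00, 0.03, 0.01, 0.03 and 0.07. MHC class II genes were higher for 8 of 10 (0.17, the 99.97th percentile of random lists), Cd74 and H2-Aa (0.30) in front and H2-DMa (-0.16) lower. Of 5 aryl hydrocarbon receptor targets with enough UMIs, Tiparp (0.77) was 1 of 2 higher in FMT_young (median -0.03). Mitochondrially encoded genes took 3.70% and 4.00% of UMIs and ribosomal protein genes 31.9% and 32.1%. Free RNA source genes, 12 in all, had a median of 0.29, with S100a8 (1.52) and S100a9 (1.5) higher and Hba-a2 and Hbb-bs lower. Xist was present in both libraries (ratio 0.13 in HSC-like cells, Tsix 0.27), while the Y-linked Ddx3y, Eif2s3y and Kdm5d had 0 UMIs in all cells of both and Uty 1 UMI in FMT_young.

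**Figure D3:**
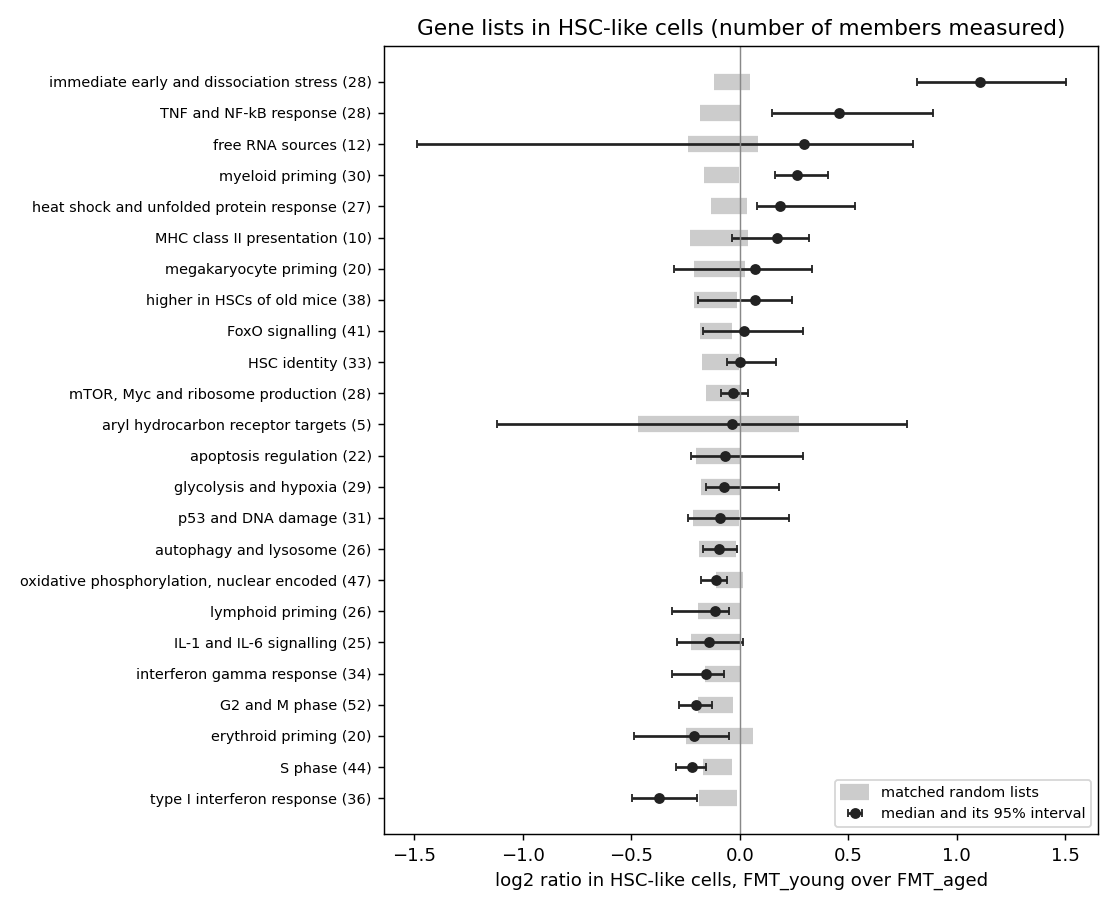
Median log2 ratio of each fixed gene list in the HSC-like class with its order-statistic interval over list members, beside the range of expression-matched random lists.

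The immediate early difference was not special to stem cells. In all 13 named classes the median of that list lay above matched random lists, from 0.45 in macrophage-like to 1.45 in mature B-like cells. TNF and NF-kB genes lay above random lists in 12 classes, all but conventional dendritic-like cells, and heat shock genes in 11. Type I interferon genes had a median below 0 in 11 classes and below random lists in 4, namely HSC-like, T, NK or innate lymphoid-like (-0.27), conventional dendritic-like (-0.15) and neutrophil-like cells (-0.30). In GMP-like cells the median was -0.10, within random lists (-0.14 to 0.03), but this depended on the processing. It ran from -0.32 to -0.12 in 11 alternatives. Interferon gamma genes were below 0 in 12 classes and below random lists in 8.

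In GMP-like cells the zinc finger immediate early gene Egr1 had 297 CPM in FMT_young and 54.4 in FMT_aged (2.45, 2.39 to 2.51), and the nucleoside diphosphate kinase gene Nme2 37.9 and 72.0 (-0.92). Monocyte progenitor-like cells had higher Ccl4 (2.07), Klf2 (1.91) and Mylip (1.93), the latter a ubiquitin ligase for the LDL receptor, and lower Cxcl2 (-1.46). Ccl4 (3.21) and Ccl3 (2.65) were higher in FMT_young monocyte-like cells and Ccl4 (2.85) in conventional dendritic-like cells. T, NK or innate lymphoid-like cells had higher Klf2 (2.09) and Fbxl18 (2.42) and lower Clec2d (-0.84). Clec2d was also lower in monocyte-like (-1.5) and neutrophil-like cells (-1.52). Neutrophil-like cells had higher Egr1 (1.91) and Polg2 (2.97). Basophil, eosinophil or mast cell-like cells had higher Nr4a1 (3.72) and Car1 (3.88, with 38.0% of the FMT_young UMIs in 1 cell), and lower Atp1b1 (-1.98) and Cxcl2 (-1.75).

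MHC class II genes differed by cell type. The list was lower in FMT_young in macrophage-like (median -1.34), plasma cell-like (-1.25), conventional dendritic-like (-0.60), plasmacytoid dendritic-like (-0.53) and monocyte-like cells (-0.19), with all 10 genes lower in both dendritic classes. It was higher in T, NK or innate lymphoid-like (0.93), mature B-like (0.41), GMP-like (0.24) and monocyte progenitor-like cells (0.11). Transcripts of other cell types were higher in T, NK or innate lymphoid-like and mature B-like cells too, free RNA source genes with medians of 0.72 and 1.72 and myeloid priming genes with 0.19 and 0.52. Free RNA source genes also differed in conventional dendritic-like (-1.04), plasmacytoid dendritic-like (1.44) and GMP-like cells (1.02). Myeloid (0.37) and lymphoid priming genes (0.46) were higher in FMT_young conventional dendritic-like cells, above random lists. At resolution 2.0, 61 FMT_young and 118 FMT_aged cells of the conventional dendritic-like class formed a cluster of their own led by genes such as Xcr1 and Naaa. In macrophage-like cells H2-Aa had 1191 and 3910 CPM (-1.72), H2-Ab1 889 and 2790 (-1.65) and H2-Eb1 989.6 and 3043 (-1.62), from 166 and 68 cells. Transcripts of other cell types moved along in that class, with medians of 5.18 for free RNA source genes, 2.01 for erythroid and 0.95 for lymphoid priming genes. At resolution 2.0 the class split into 105 FMT_young and 29 FMT_aged macrophage-like cells and 61 and 39 monocyte-like cells, so its cells were not the same mix in the 2 libraries. Plasma cells were not the same mix either, with 898 FMT_young and 5 FMT_aged cells in cluster 9 and 232 and 678 in cluster 8. Their MHC class II and cell cycle medians therefore compare different clusters. In plasmacytoid dendritic-like cells H2-Ab1 (-0.94) was lower, and so were S100a4 (-1.55) and Ifitm3 (-1.04), with 40.6% and 42.7% of their FMT_aged UMIs in 1 cell. Cell cycle genes also went apart. All 44 S phase and all 52 G2 and M phase genes were higher in FMT_young conventional dendritic-like cells (medians 0.39 and 0.39), while all 52 G2 and M phase genes were lower in basophil, eosinophil or mast cell-like cells (-0.54, S phase -0.33). The latter class pools clusters 15, 26 and 27, of which cluster 26 was shallow (49 and 92 cells, medians of 1827 and 3034 UMIs). Free RNA source (1.33) and erythroid priming genes (0.38) were higher in FMT_young in that class. Mature B-like (-0.86 and -1.48) and plasma cell-like cells (-0.60 and -0.79) had lower S and G2 and M phase medians, and neutrophil-like cells a lower G2 and M phase median (-0.54), while the thinned shares of cells with 3 G2 and M phase genes were near each other in mature B-like (38.0% and 41.8%, with 82 and 72 shallower cells left out) and neutrophil-like cells (47.6% and 48.5%, with 56 and 61 left out) and in plasma cells, as given before. Unthinned they were 57.8% and 70.9% in mature B-like and 81.7% and 79.7% in neutrophil-like cells. Of the mature B-like cells, 20 in FMT_young and 64 in FMT_aged formed a pro-B or pre-B-like cluster led by Ebf1, Vpreb3 and Vpreb1 at resolution 2.0. In mature B-like cells Nr4a1 was higher (3.39), and Dntt (9 and 274 UMIs), Cd36 (7 and 231) and Ly6k (11 and 210) were lower.

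Several of the genes with the largest ratios in small classes came mostly from 1 cell. This held in FMT_young for Igha in conventional dendritic-like cells (82.4% of the UMIs of the gene), Ltf and Ngp in mature B-like cells (88.3% and 81.5%), Retnla in neutrophil-like cells (99.6%), Ccl5, Jchain and Igkc in neutrophil progenitor-like cells (97.7%, 65.9% and 63.4%), Hbb-bt in macrophage-like cells (62.3%), and Retnlg, S100a8 and S100a9 in plasmacytoid dendritic-like cells (70.1%, 58.1% and 51.4%). In FMT_aged it held for Stfa1, Camp and Ngp in conventional dendritic-like cells (64.8%, 68.1% and 59.4%), BC100530 in basophil, eosinophil or mast cell-like cells (79.2%) and Ighd in plasma cells (77.3%). Igkc in conventional dendritic-like cells also had 67.1% of its FMT_aged UMIs in 1 cell. That gene was higher in FMT_young (2.5), so this cell made its ratio smaller. S100a8 (9046 and 181 CPM) and Lcn2 (822 and 10.3) in macrophage-like cells are transcripts of neutrophils, with 23.8% and 26.6% of their FMT_young UMIs in 1 cell. In barcodes with under 100 UMIs S100a8 stood at 9375 and 6104 CPM. Its ratio there (0.62) was far smaller than in macrophage-like cells (5.645). BC100530 in neutrophil progenitor-like cells was lower in FMT_young (49 and 252 UMIs, -2.72).

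**Figure D4:**
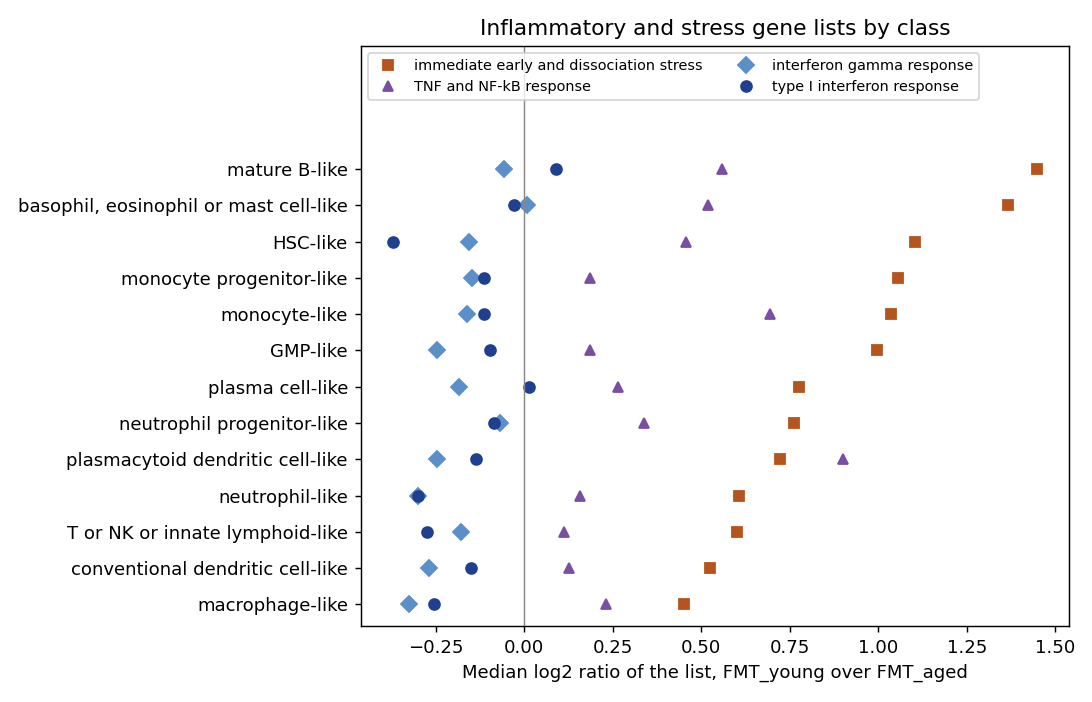
Median log2 ratio of the type I interferon, interferon gamma, TNF and NF-kB, and immediate early lists in each of the 13 classes.

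Different V genes led in the plasma cells of the 2 libraries, and 1 light and 1 heavy chain V gene led in most of the counted cells in FMT_young only. In FMT_young, Igkv1-117 (ENSMUSG00000094335, chromosome 6, 68121046 to 68121827) was the leading light chain V gene in 797 of the 915 plasma cells with at least 10 light chain V UMIs (87.1%, 84.8 to 89.2%), and Ighv1-19 the leading heavy chain V gene in 176 of 217. In FMT_aged, Igkv6-15 led in 192 of 401 cells (47.9%, 42.9 to 52.9%) and Ighv1-26 in 33 of 117. The inverse Simpson index of leading light chain V genes was 1.32 in FMT_young and 4.00 in FMT_aged, and that of heavy chain V genes 1.51 and 8.29. Ighm was the leading constant gene in 95.7% and 94.6% of plasma cells, and immunoglobulin genes took 61.2% and 60.2% of their UMIs. Of 1130 FMT_young plasma cells, 787 had at least 10 UMIs of Igkv1-117, and 754 of these also had Ighv1-19. In FMT_aged, 2 of 683 plasma cells reached that level and Ighv1-19 had 0 UMIs in plasma cells. Ighv1-26 (-5.75) and Igkv3-2 (-3.38) were lower in FMT_young plasma cells, and the growth arrest gene Gadd45g (2.24), Vegfa (2.20) and Dusp5 (1.96) were higher.

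Immunoglobulin transcripts were also higher in FMT_young in cells that should make none. They took 0.187% and 0.0837% of UMIs in HSC-like cells (1.16), 0.900% and 0.184% in GMP-like cells (2.29) and 0.578% and 0.161% in T, NK or innate lymphoid-like cells (1.85), and were lower in FMT_young in mature B-like cells alone (-0.55). Igkc had a ratio of 2.34 in GMP-like cells. It had 1.92 in T, NK or innate lymphoid-like, 2.5 in conventional dendritic-like and 2.77 in monocyte-like cells, and Igha had 3.57 in GMP-like cells, but 37.4%, 33.2%, 30.6% and 39.8% of these FMT_young UMIs came from 1 cell of the class. Igkv1-117 had 186 and 1 UMIs in basophil, eosinophil or mast cell-like cells, 29.0% of the former in 1 cell. In barcodes with under 100 UMIs, Igkc stood at 53120 CPM in FMT_young and 28080 in FMT_aged. From the levels of granule and globin genes, free RNA made up at most 1.62% of HSC-like UMIs in FMT_young and 1.02% in FMT_aged.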

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

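The weighing of explanations was set up after the results were seen, with the test without the cells richest in interferon genes, the narrow cluster, the count of classes and the level of Igkv1-117, and the explanation by makeup was added once its value was known, while free RNA subtraction and cells chosen by HSC transcripts were alternatives fixed before.

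Barcodes with under 100 UMIs, which were not called as cells and enter the comparisons only through the free RNA profile, drew notice as a signal in data outside the main measurement. Igkv1-117 stood there at 166 CPM in FMT_young and 0.780 in FMT_aged, and Igkv6-15 at 0.488 and 30.4. Gm42418, from a locus with ribosomal RNA sequence, stood at 4332 and 11370. With 1 library per group no difference between these values was tested.

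Type I interferon genes had a median ratio of -0.37 in HSC-like cells. The tables argue against a few interferon-rich cells of FMT_aged as the whole cause, because without the 1% of cells richest in these genes in each library the median was -0.26 (interval -0.40 to -0.15), still below matched random lists (-0.18 to -0.01). A different makeup of the class, with cells that lack HSC transcripts, may still explain it: among cells chosen by HSC transcripts the median was -0.089, within random lists, while in the narrow cluster found without interferon genes it was -0.24, below random lists (-0.20 to 0.10), so the sets differ and makeup remains open. The age of the microbiota donors remains open and untested, since it cannot be told apart from any other difference between libraries with 1 library per group.

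Immediate early genes had a median ratio of 1.10 in HSC-like cells. Free RNA is argued against, because after its subtraction from the HSC-like class the median was again 1.10, above matched random lists. Handling of the FMT_young library before capture, such as time or warmth during sorting, is a candidate explanation, as it would act on every cell type: the list lay above random lists in 13 of 13 classes, mature cells included. The age of the donors remains open too, since 1 library per group cannot separate it from handling.

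Plasma cells rich in Igkv1-117 were 787 of 1130 plasma cells in FMT_young and 2 of 683 in FMT_aged. Free RNA is argued against as their source, because Igkv1-117 stood at 1317 CPM in FMT_young plasma cells and at 166 in the free RNA profile. An expanded plasma cell clone in an animal of that library may account for the pattern, but with 1 library per group this cannot be told apart from an effect of the donors' age, which remains open.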

How the results depend on the processing

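The clustering without gene families, the class with the Cd34 clusters, the class without the cells richest in interferon genes, and shares without single clusters or plasma cells were chosen after the data were seen. No paired analysis was possible because each group has 1 library and the labels pair none. Unless said otherwise, values are log2 ratios, and the cause of a shift was not tested.

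For the results that answer a comparison, the alternatives fixed beforehand left 129 values within the interval of the value first given, moved 50 and reversed 14, and those chosen later left 31, moved 13 and reversed 2. A value was counted as reversed only where the first interval left out 0, so values of opposite sign are also among the others, such as genes of old HSCs (first 0.07) and cells with 3 G2 and M phase genes (first -1.51 points). For the other values the counts were 590, 122 and 17, and 132, 31 and 6. The medians of type I interferon (-0.63 to -0.09), interferon gamma (-0.42 to -0.06), TNF and NF-kB (0.17 to 0.55) and immediate early genes (0.49 to 1.20) kept their sign in all 19 alternatives, and so did the GMP-like share in 14 (0.09 to 0.49 of all cells). Random lists lie below 0 themselves, and the type I interferon difference was lost in cells chosen by HSC transcripts, at the 62.2nd percentile of random lists, while interferon gamma was within their central range already at first (3.09th percentile). Klf2 (1.70 to 3.01), Nr4a1 (1.37 to 2.75), Lars2 (-1.69 to -1.15) and AY036118 (-1.45 to -1.15) did so in 17.

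Each library clustered on its own changed most, because the HSC-like cluster held 715 FMT_young and 83 FMT_aged cells while 887 FMT_aged cells fell to a cluster named MPP-like. The HSC-like share was 3.04 of all cells and 2.96 of progenitor clusters, the GMP-like share 0.18 and 0.092. HSC-like medians were 1.87 for S phase, 0.78 for G2 and M phase, 0.98 for lymphoid priming, 0.58 for myeloid priming, -2.19 for genes of old HSCs, 0.49 for immediate early, -0.42 for interferon gamma, -0.63 for type I interferon and 0.25 for oxidative phosphorylation genes. Dntt was 4.71, Ifi27 0.0002, and cells with 3 G2 and M phase genes differed by 6.52 percentage points.

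At resolution 2.0, where clusters were also named MPP-like, its share was 0.11 of all cells and 0.29 of progenitor clusters, the GMP-like share 0.086 and 0.085 and the monocyte progenitor share of progenitor clusters 0.11. HSC-like medians were 0.0072 for G2 and M phase, 0.016 for S phase, -0.24 for genes of old HSCs, -0.0093 for myeloid, 0.058 for erythroid and 0.0027 for autophagy genes, and Hbb-bt was 0.075. At resolution 0.5 the GMP-like share of progenitor clusters was 0.31.

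Clustered without immunoglobulin, histone, interferon, immediate early and cell cycle genes, the HSC-like share was -0.065 of all cells and -0.060 of progenitor clusters, the GMP-like share 0.20 and 0.21, the basophil, eosinophil or mast cell share 0.069 and 0.073 and the monocyte progenitor share 0.027 and 0.032. HSC-like medians were -0.28 for G2 and M phase, 0.16 for S phase, -0.39 for lymphoid and -0.061 for myeloid priming.

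Classes by marker score per cell gave HSC-like shares of -0.28 and -0.15, GMP-like shares of 0.17 and 0.30, Dntt 1.08, S phase -0.42, lymphoid priming -0.049, myeloid priming 0.50 and a difference of -6.96 points in cells with 3 G2 and M phase genes. HSC-like cells by transcripts gave -0.62 for G2 and M phase, -0.41 for S phase, -7.56 points for cells with 3 such genes, -0.043 for myeloid and 0.039 for erythroid priming, -0.089 for type I interferon and 0.62 for Hbb-bt. The myeloid and erythroid values are partly set by the choice of these cells, which leaves out cells with Mpo, Elane, Klf1 or Car1 of those lists. With the Cd34 clusters added, S phase was -0.14, autophagy 0.0098, lymphoid priming -0.0007 and type I interferon -0.19.

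At least 500 UMIs and 250 genes gave GMP-like shares of 0.46 and 0.15. At least 2000 UMIs gave 0.18 and 0.30, HSC-like shares of -0.30 and -0.17, a monocyte progenitor share of progenitor clusters of 0.081 and lymphoid priming of 0.047. The UMI minimum set per library gave GMP-like shares of 0.11 and 0.25 and a monocyte progenitor share of progenitor clusters of 0.028. It named no HSC-like cluster, so it gave no HSC-like value.

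At most 5% mitochondrial UMIs gave a GMP-like share of 0.28 of all cells, HSC-like shares of -0.24 and -0.19, a mature B share of 0.081, lymphoid priming -0.041 and myeloid priming 0.094. At most 20% gave GMP-like shares of 0.10 and 0.033, Dntt 0.36, G2 and M phase -0.42, S phase -0.30 and lymphoid priming 0.25. No doublet removal gave GMP-like shares of 0.10 and 0.21, an HSC-like share of progenitor clusters of -0.28, a conventional dendritic cell share of 0.0056, Dntt 0.065, S phase -0.34, lymphoid priming 0.09 and myeloid priming 0.51.

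TMM scaling, which adds 0.10 to every ratio by construction, gave -0.10 for G2 and M phase, -0.12 for S phase, 0.0042 for autophagy, -0.056 for interferon gamma and -0.013 for lymphoid priming. Without the shallow GMP-like cluster the GMP-like shares were 0.17 and 0.25 and the HSC-like share of progenitor clusters -0.32. Without plasma cells rich in Igkv1-117, which removes 787 FMT_young and 2 FMT_aged cells, the plasma cell share was -0.95 and the GMP-like share of all cells 0.49.

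In the clustering used throughout no cluster was named MPP-like, because the treatment of ties, set after the clusters had been looked at, left the 2 Cd34 clusters unnamed, so these took the place of the planned union of HSC-like and MPP-like cells. Small sets hold few UMIs: cells chosen by HSC transcripts were 92 and 133, with 587586 and 905940 UMIs, and list members with few UMIs, such as Mx1 with 5 and 37, have wide intervals.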

Other observations

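The values in this part were looked at after the main results were seen. A cluster of NK-like cells (cluster 3, led by Xcl1, Klra8, Cd7 and Il2rb) had UMIs of Kit in 49.8% of its 620 FMT_young and 50.8% of its 862 FMT_aged cells, at medians of 3951 and 3626 UMIs. In the T cell cluster (cluster 13, with Ccl5, Trbc2 and Cd3e among its leading genes) the shares were 1.22% and 1.78%, at medians of 2810 and 2611 UMIs. The conventional dendritic-like cluster had Kit in 52.5% and 58.0% of cells, at medians of 12620 and 11040 UMIs, and the HSC-like cluster in 76.4% and 78.1%.

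Plasma cells in both libraries had Ighm as the leading constant gene in 95.7% of FMT_young and 94.6% of FMT_aged cells, and Igha in 3.81% and 4.70%. Beside Igkv6-15, FMT_aged plasma cells had Igkv3-2 as the leading light chain V gene in 38 of 401 cells and Ighv7-3 as the leading heavy chain V gene in 15 of 117. In FMT_young the next light chain V genes were Igkv3-4 and Iglv1, with 10 of 915 cells each, and the next heavy chain V gene was Ighv11-2, with 8 of 217. Outside the plasma class, 85 of 9663 FMT_young and 2 of 9637 FMT_aged cells had at least 10 UMIs of Igkv1-117.

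Cluster 29, unnamed, held 54 FMT_young cells and 0 FMT_aged cells, with a median of 3424 UMIs. Cluster 25, unnamed and led by Fcnb and immunoglobulin genes, held 113 and 42 cells with medians of 41800 and 43890 UMIs. In barcodes with under 100 UMIs, Malat1 stood at 16430 CPM in FMT_young and 9845 in FMT_aged, Klf2 at 677 and 226, Ighm at 30810 and 14110, Mpo at 5553 and 6132 and Elane at 5249 and 4781.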
